A study of Mus musculus with 8 samples.

How the data were processed

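The study measured liver RNA of AIM+/+ (wild-type) and AIM-/- (knockout) mice on 8 one-colour Agilent Whole Mouse Genome arrays, 1 array for each genotype at 0 (normal chow), 6, 12 and 20 weeks of high-fat diet. The processed signal intensity of each spot was made with Agilent Feature Extraction 9.5, per the submitters' processing notes. Background was subtracted and spatial trends were removed, per the file headers (Feature Extraction 9.5.3.1, protocol GE1-v5_95_Feb07, array design 014868). The deposited value table holds log2 values. A comparison of its columns with the scanner files showed that each is the log2 processed signal, with the spots of a probe averaged, minus the array's 75th percentile. The raw mean and local background intensity of each spot are also in the deposited scanner files, and only an alternative background correction used them.

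All values started from the processed signal intensity. The 1639 control spots and the spots that the scanner software marked as outliers (75 to 130 per array) were left out. Spots of a probe were averaged, and log2 values were scaled by subtracting each array's 75th percentile. Of 41174 probes, 21388 were well above background, by the scanner software's own mark, on at least 2 of the 8 arrays and were kept. The probe with the highest mean stood for a gene with more than 1 probe. This left 15340 genes, 12016 of them with a gene symbol. Probe accessions were matched to current symbols through a RefSeq table of the GRCm38 assembly, used for names only (24375 probes matched and 16799 did not). The unmatched probes kept the name in the file. Coordinates are those of the array files, on mm8.

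Genes were tested with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package for reading. A linear model with the week of diet as a factor of 4 levels and with genotype left 3 residual degrees of freedom. Its 3 contrasts were knockout minus wild type, the mean of 6, 12 and 20 weeks minus chow, and 20 minus 6 weeks. Weeks stand in for replicates of a genotype and genotypes for replicates of a week, so these p-values measure the spread between these 8 arrays and not that between animals of a group. The interaction of genotype with diet came from a model of 4 cells (genotype by chow or any week of diet) with 4 residual degrees of freedom. The lone chow array of each genotype is assumed there to vary like the others. Benjamini-Hochberg adjusted p under 0.05 was the threshold. At a single week, 1 array stands against 1, so no test was made: genes at least 2-fold different, with signal well above background on at least 1 of both arrays, were counted. If only some arrays of the lower group were well above background, the size is printed as measured but rests partly on background. Where the lower group was not well above background on any array, the fold is a lower bound against the lowest signal marked as well above background, written as at least N-fold. For lists that passed by genotype, diet or 20 minus 6 weeks, the median with such genes at their bound (with bounds) is added where it differs.

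The 37 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 731 entries, of which 623 were measured. They cover the cell types of the liver and of possible neighbouring tissue, lipid, glucose, bile acid and xenobiotic metabolism, stress, inflammation, complement, the cell cycle, tumour markers, the circadian clock, sex-biased expression, neighbours of Cd5l and genes known to differ between strains used in gene targeting. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the residuals. Those residuals have only 3 degrees of freedom. The estimated correlation was not tried on simulated lists, so the power of that setting is unknown. The rotation test fry stood beside camera. Single-week list medians are given as percentiles among 10000 random lists of the same size, matched on mean expression. These medians and the counts of members at least 2-fold apart used every measured member. They applied neither the mark for signal well above background nor the lower bounds. The rule named Cd5l first, then the 12 largest rises and the 12 largest falls past the threshold with the same sign in every week or in both genotypes, or the 5 smallest p where fewer than 3 passed. For single weeks it named the 5 largest differences each way, and for lists the members past the threshold and up to 4 with the largest coefficient.

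The fits were tested on simulated data with the real genes, 200 of them changed, each with its mean and its residual spread from the real arrays. For genotype they recovered 56% of genes changed 2-fold and 92% of those changed 8-fold, with 6 false among 167 calls. For diet the shares were 38% and 82% (10 false of 154 calls), for 20 minus 6 weeks 24% and 92% (3 of 136), and for the interaction 2% and 66% (6 of 96). In the diet comparison, 2 of 2 shifted lists were recovered and 1 other list passed. The simulated noise was independent between genes and held no change between weeks of diet. The interaction model counts such change as error, so its shares are likely too high.

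The share of probes well above background ran from 45.1% to 51.3% per array and no spot was saturated. The number of arrays limits the precision. All 4 wild-type arrays lie on 1 slide and all 4 knockout arrays on another, scanned separately, with the weeks in the same positions, so slide and genotype cannot be told apart. Alternatives were quantile normalization, normexp background correction with an offset of 50, other filters and probe rules, the deposited value table, another variance prior, other model terms, and each array or week left out in turn. Others were chosen after seeing the data: the fits without the 20-week arrays, the genotype lists without genes within 20 Mb of Cd5l, and the list tests for 20 minus 6 weeks with their alternatives. A slide block was not run because it is the genotype term itself.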

Results

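Gene expression was measured in the livers of AIM+/+ and AIM-/- mice on a C57BL/6 background. AIM (apoptosis inhibitor of macrophage) is a secreted protein of tissue macrophages encoded by Cd5l. Mice were fed normal chow (0 weeks) or a high-fat diet for 6, 12 or 20 weeks, and 1 array was hybridised for each genotype at each time, 8 arrays in all. No group has a replicate, so each test below draws its error from the spread across weeks or across genotypes. Between 18589 and 21120 of 41174 probes per array were well above background, and 15340 genes were compared.

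The targeted gene separated the genotypes on every array. The Cd5l signal was 10544, 19978, 30201 and 23802 in the wild type at 0, 6, 12 and 20 weeks, and 90.7, 140, 171 and 150 in the knockout. These knockout signals were still well above background on 4 of 4 arrays. Across the weeks Cd5l fell by 7.35 on the log2 scale in the knockout (SE 0.12, 4 arrays per genotype, 163-fold, adjusted p = 0.000331). Its probe lies on chromosome 3 at 87456828 to 87456887 (mm8). Whether that position falls inside the deleted part was not analysed here.

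The genes of the sex chromosomes separated the 20-week arrays from all others. Xist, the RNA that silences an X chromosome in females, gave scaled log2 signals of 3.80 and 3.70 on both 20-week arrays with its brightest probe, against -4.31 on the highest of the other 6. Another Xist probe was well above background on 4 arrays, with signals of 903 and 892 at 20 weeks, 165 on the knockout array at 6 weeks and 66.1 on the wild-type array at 12 weeks. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background on the 6 other arrays and on neither 20-week array. Their mean difference between 12 weeks and chow was -0.28.

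**Figure D1:**
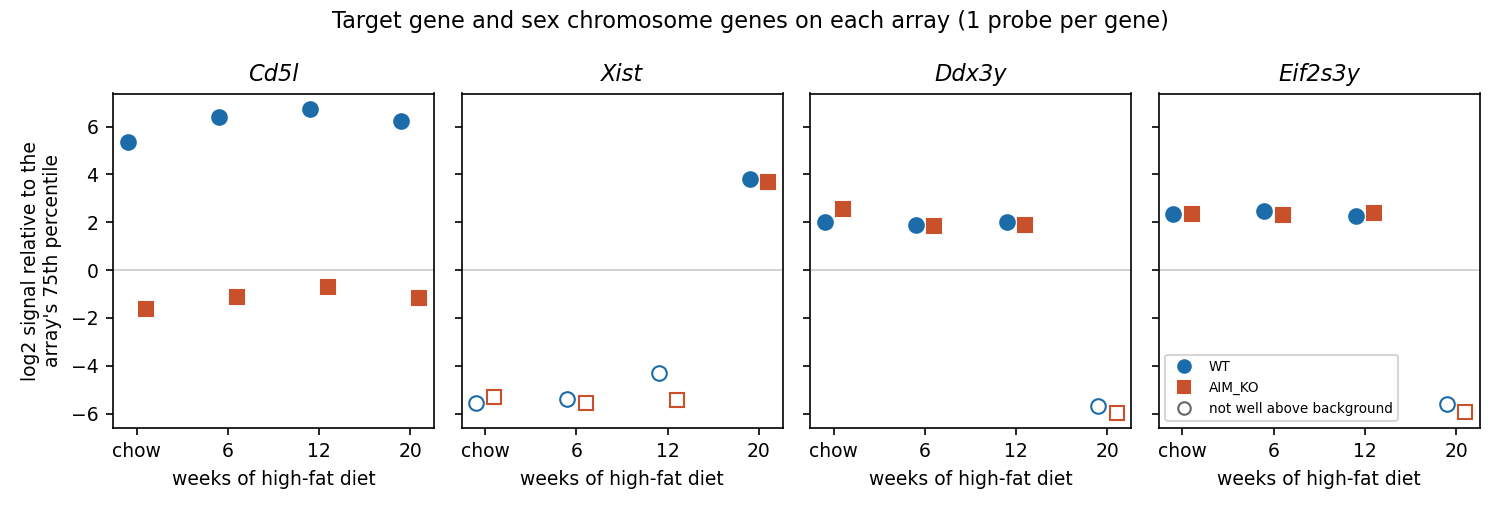
Log2 signal relative to the array's 75th percentile (vertical axis) of Cd5l, Xist (its brightest probe), Ddx3y and Eif2s3y on each of 8 arrays, by weeks of high-fat diet (horizontal axis); circles are wild type, squares knockout, and open symbols are not well above background. Cd5l is lower on the 4 knockout arrays, and Xist reaches 3.80 and 3.70 on the 20-week arrays, where Ddx3y and Eif2s3y are not well above background.

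The comparison of genotypes over all weeks asked which liver transcripts differ steadily when AIM is absent. Besides Cd5l, 4 genes passed. Asic5, an acid-sensing ion channel family member, was higher in the knockout by 3.29 (SE 0.14, log2, 9.79-fold, adjusted p = 0.0111), and Wars2, the mitochondrial tryptophanyl-tRNA synthetase, by 2.28 (SE 0.14, 4.86-fold, adjusted p = 0.0428). The transcripts 1700112E06Rik and BB098755 were lower, by -2.77 (SE 0.13, 6.81-fold, adjusted p = 0.0137) and at least 2.03-fold (adjusted p = 0.00586). Each kept its direction in all 4 weeks.

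Asic5 and Wars2 lie on chromosome 3, as Cd5l does, at 82100360 and 99348148 (mm8), 5.36 and 11.9 Mb away. 1700112E06Rik and BB098755 lie on chromosome 14, at 21844556 and 68415939. Among the genes closest to the threshold, Ppm1l, a protein phosphatase, had a difference of 0.79 (SE 0.08, adjusted p = 0.204) and the transcript ENSMUST00000062945 one of at least 6.60-fold (adjusted p = 0.0724). Both also lie on chromosome 3.

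Of the 37 lists, 4 passed at the preset correlation of 0.01. The neutrophil markers were lower in the knockout (7 of 8 members negative, median -0.39, adjusted p = 0.00156, and adjusted p = 0.94 with an estimated correlation). S100a9 and S100a8, the subunits of calprotectin, had -1.28 (SE 0.19) and -1.16 (SE 0.22), and lie 3.32 and 3.3 Mb from Cd5l. No member passed over all genes, and 2 fell adjusted over the list alone. Kupffer cell and macrophage markers, with Cd5l left out, were lower (16 of 19 negative, median -0.17, adjusted p = 0.0191, and adjusted p = 0.94 with an estimated correlation), with -1.20 (SE 0.49) for the haemoglobin scavenger receptor Cd163, -1.06 (SE 0.35) for the scavenger receptor Marco and -0.93 (SE 0.36) for Timd4. Itgax, the dendritic cell and macrophage integrin CD11c, stood the other way at 0.65 (SE 0.41).

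Complement component genes were lower (19 of 22 negative, median -0.13, adjusted p = 0.0192, and adjusted p = 0.94 with an estimated correlation), with -0.77 (SE 0.63) for factor D (Cfd) and -0.53 (SE 0.10) for the lectin Fcna. C1qa, C1qb and C1qc belong to this list and to the Kupffer cell list. T and NK cell markers were higher (13 of 14 positive, median 0.21, 0.17 with bounds, adjusted p = 0.0192, and adjusted p = 0.94 with an estimated correlation), with 0.76 (SE 0.31) for the chemokine Ccl5 and 0.36 (SE 0.28) for Cd3d. No member of these 3 lists passed, either over all genes or adjusted over the list alone. The rotation test fry passed 0 of 37 lists (smallest adjusted p = 0.949).

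The other 33 lists did not pass, at adjusted p from 0.0515 (male-biased liver genes, median -0.20) to 0.94. They include lipid droplet genes (0.09, adjusted p = 0.0529), lipid-associated and recruited macrophage genes (0.16, adjusted p = 0.0529), hepatocellular carcinoma and fetal liver genes (0.08, adjusted p = 0.635) and complement regulators and receptors (-0.04, adjusted p = 0.656). The 18 measured neighbours of Cd5l had a median of 0.11 (adjusted p = 0.386). Of 12 genes known to differ between strains used in gene targeting, none passed over all genes (median 0.04, adjusted p = 0.662), and adjusted over the list alone Erdr1 was higher (1.55, SE 0.28) and Entpd4 lower (-0.74, SE 0.09). Entpd4 lies on chromosome 14.

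In total 5 genes passed (2 higher, 3 lower) and 859 had an unadjusted p under 0.05, against 767 expected by chance. Without any 1 of the weeks only Cd5l passed. The Kupffer cell call ended without 6 weeks (adjusted p = 0.138) or 20 weeks (adjusted p = 0.458), the T and NK cell call without 12 weeks (adjusted p = 0.585) and the complement call without 6 weeks (median 0.01, adjusted p = 0.764). The neutrophil call ended without genes within 20 Mb of Cd5l, S100a8 and S100a9 among them (remaining median -0.32, adjusted p = 0.0721). The 4 lists became 16 (11 higher, 5 lower) without the 20-week pair and 8 (4 higher, 4 lower) without the chow pair, in place of 1 higher and 3 lower. Genotype and slide cannot be told apart in these values.

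**Figure D2:**
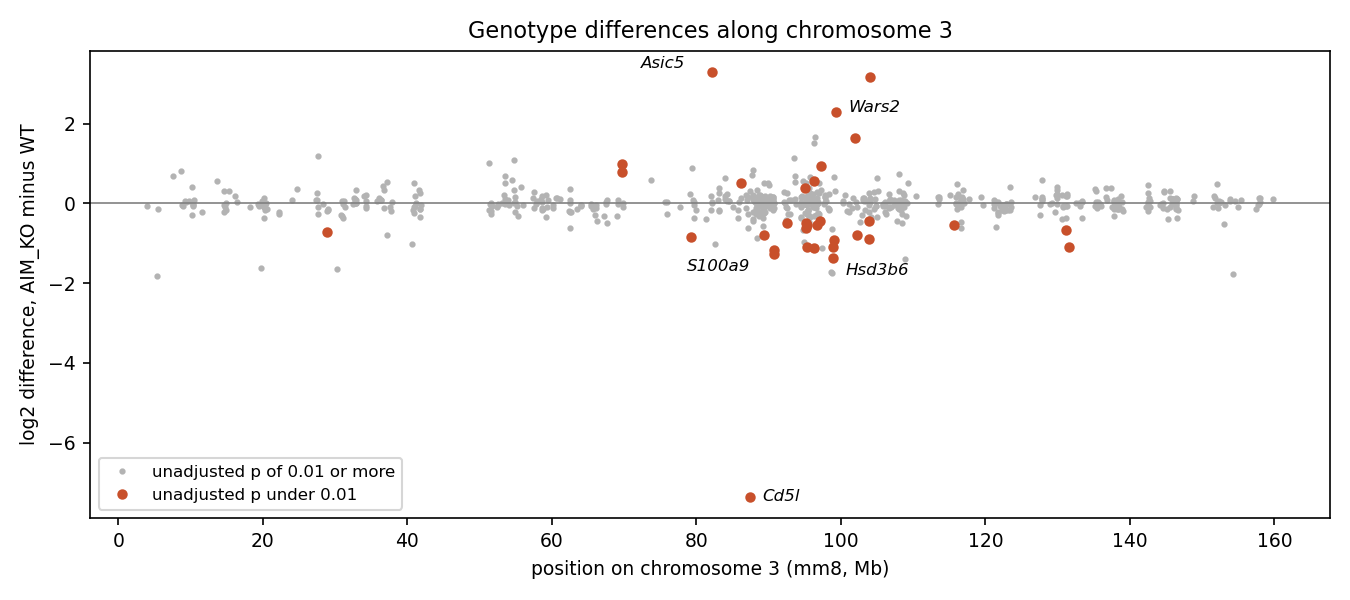
Log2 difference between knockout and wild type (vertical axis, mean over 4 weeks) for each gene on chromosome 3 by its mm8 position in Mb (horizontal axis); orange points have an unadjusted p under 0.01. Of 32 such genes besides Cd5l, 28 lie within 20 Mb of Cd5l.

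At each single week the genotypes were set side by side, 1 array against 1, to ask when the livers differ most. On chow, the knockout liver had 30.8-fold more Tff3, a trefoil peptide of mucosal epithelia (signal 7957 against 232), at least 135-fold more Moxd1, a monooxygenase of the DBH family (3468 against 5.58), and 37.9-fold less G6pc, the catalytic subunit of glucose-6-phosphatase (899 against 30558). The median of the circadian clock genes stood 0.81 higher in the knockout (percentile 100 of 10000 random lists), with members going both ways. Of its 20 members 14 were higher, 9 of them at least 2-fold, and 3 were at least 2-fold lower. The median of the inflammatory cytokine genes stood 0.67 higher (percentile 100). Medians were lower for lipogenesis genes (-0.50, 8 of 23 at least 2-fold lower, percentile 0) and cholesterol synthesis genes (-0.55, 8 of 26, percentile 0). Cytokine genes were also higher at 6 and 12 weeks (0.22 and 0.66) but lower at 20 weeks (-0.41, percentile 0). Lipogenesis genes were higher at 6 and 20 weeks (0.15 and 0.30, percentile 100 for each) and lower at 12 weeks (-0.35, percentile 0).

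At 6 weeks, besides Cd5l, sex-biased liver genes differed. The female-biased cytochrome Cyp2b9 stood 7.20 higher in the knockout (147-fold, 11295 against 59.4) and Cyp2b13 at least 72.8-fold higher, while the male-biased Hsd3b5 was 83.7-fold lower (154 against 9996) and its neighbour Hsd3b4 71.6-fold lower. On this knockout array Ddx3y, Eif2s3y and Kdm5d were well above background. Lipid droplet genes stood 0.66 higher (8 of 22 at least 2-fold, percentile 100), lipid-associated and recruited macrophage genes 0.76 higher (11 of 12 members higher, percentile 100) and stellate cell and fibrosis genes 0.47 higher (8 of 26 at least 2-fold, percentile 100). Complement component genes were lower in 22 of 22 members (median -0.48, percentile 0), and acute phase genes had a median of -0.56 (percentile 0). Hsd3b1, Hsd3b3 and Hsd3b6, paralogs of Hsd3b5, lie 11.4 to 11.5 Mb from Cd5l on chromosome 3. Over all weeks they had -0.92, -1.10 and -1.37 in the knockout and did not pass.

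At 12 weeks the hepatocellular carcinoma and fetal liver genes stood 0.96 higher in the knockout (9 of 21 at least 2-fold, percentile 100), T and NK cell markers 0.74 higher (6 of 14, percentile 100) and endoplasmic reticulum stress genes 0.44 higher (21 of 22 members higher, percentile 100). The stress list stood the other way at 6 weeks (-0.48, 4 of 22 members higher, percentile 0), and at -0.10 on chow and 0.12 at 20 weeks. Bile acid genes had a median of -0.27 (percentile 0). At 20 weeks, where both arrays carried Xist signal, immediate early genes were lower in the knockout (median -1.57, 19 of 20 at least 2-fold lower, percentile 0), as were Kupffer cell markers (-0.48, 19 of 19 members lower, percentile 0), neutrophil markers (-0.80, percentile 0) and hepatocellular carcinoma and fetal liver genes (-0.48, percentile 0). Lipid-associated and recruited macrophage genes (-0.51, 1 of 12 members higher) and stellate cell and fibrosis genes (-0.28, 3 of 26) were lower too, each at percentile 0. At 12 weeks both lists had stood higher in the knockout (0.41 and 0.20), as at 6 weeks. Cholesterol synthesis genes stood 0.27 higher at 20 weeks (24 of 26 members, percentile 100).

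Genes at least 2-fold apart numbered 1112 on chow (447 higher and 665 lower in the knockout), 1007 at 6 weeks (469 and 538), 699 at 12 weeks (389 and 310) and 638 at 20 weeks (305 and 333). Both arrays were well above background for 550, 489, 287 and 314 of them, so that 20 weeks then had more than 12 weeks. Normexp background correction gave 400, 352, 216 and 205. Across genes, which are not independent replicates, the differences of any pair of weeks had a correlation between -0.00225 and 0.104. These single-week differences have no replicate check. The single-week list medians and member counts used every measured member, whether or not it was well above background that week. The percentiles set a list against random genes, so a list whose members move together can reach an extreme between any pair of livers.

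High-fat diet was compared with chow in both genotypes together, to show how the liver differed on it. Chow arrays exist at 0 weeks alone, so the diet cannot be told apart from age or the time passed in any value of this comparison or of the interaction below. Of the 6 diet arrays, 2 carried Xist signal and no Y-linked signal, while both chow arrays carried Y-linked signal. Sizes of this comparison from all arrays may therefore mix sex with the diet. Lipid droplet and triglyceride storage genes rose: Cidea, a lipid droplet fusion protein, by 7.58 (SE 0.80, log2, adjusted p = 0.0362), Cidec, its relative, by 4.75 (SE 0.40, adjusted p = 0.0268), the apolipoprotein Apoa4 by 4.72 (SE 0.68, adjusted p = 0.0493) and the acyltransferase Mogat1 rose 16-fold (adjusted p = 0.0467). Among the lists, 9 of 28 cell cycle genes, 6 of 28 interferon response genes and 4 of 31 genes of fatty acid oxidation rose, and 4 of 19 male-biased liver genes fell. Each of these list calls ended with an estimated correlation (adjusted p = 0.432 with an estimated correlation). Lcn2, an iron-sequestering acute phase protein, rose by 3.82 (SE 0.25, 14.1-fold, adjusted p = 0.0237) and Spp1, osteopontin, by 3.52 (SE 0.47, 11.5-fold, adjusted p = 0.0467). Here 2 chow arrays stood against 6 on the diet. Cidea was well above background on 1 of these 2 chow arrays, so its size rests partly on background.

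**Figure D3:**
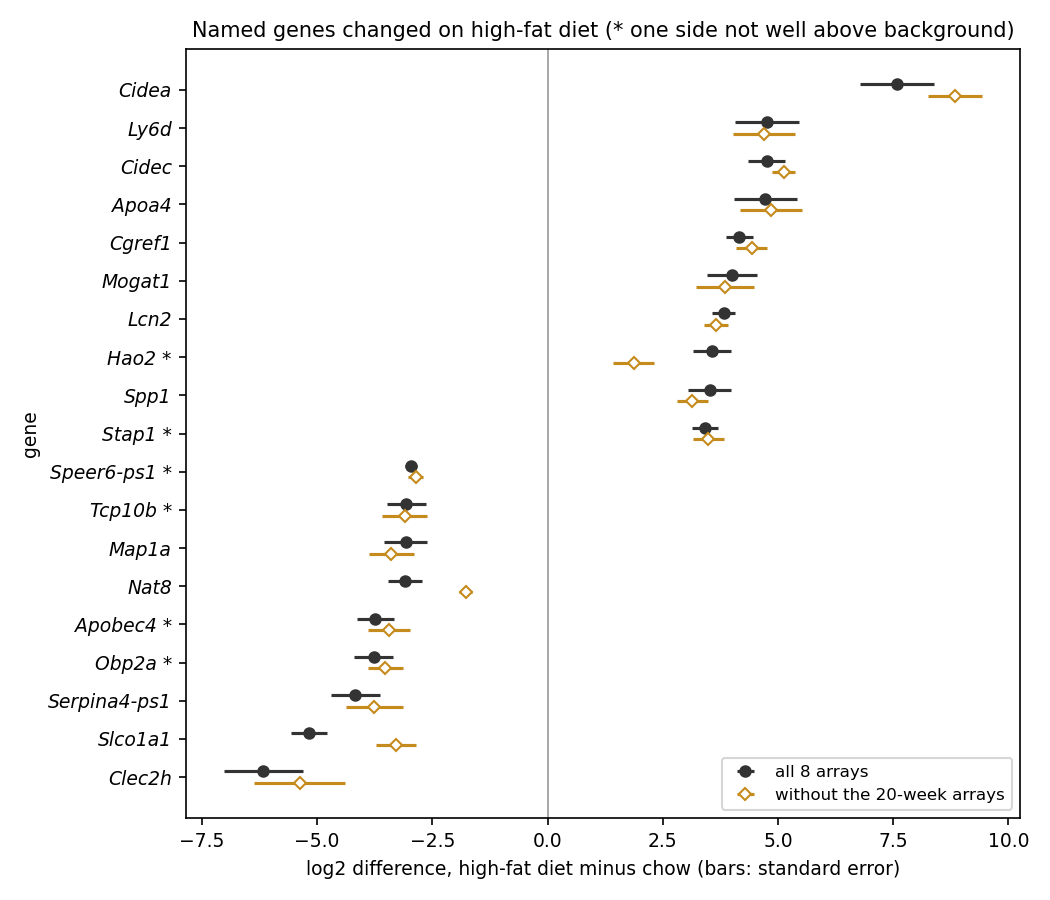
Log2 difference between high-fat diet and chow (horizontal axis; bars are standard errors) for the named genes (vertical axis), in all 8 arrays (filled) and without the 20-week arrays (open); for genes with an asterisk 1 side is not well above background and the size is no measured fold. Cidea stands at 7.58 with all arrays and 8.84 without those of 20 weeks. Slco1a1 moves from -5.18 to -3.29 and Nat8 from -3.09 to -1.78. The sizes of Cidea, Clec2h, Slco1a1, Serpina4-ps1 and Map1a rest partly on signals not well above background.

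In the lipid droplet list 7 of 22 measured members rose, 0 fell and 15 did not pass, and 15 rose adjusted over the list alone (median 1.22, adjusted p = 1.9e-10, and adjusted p = 0.432 with an estimated correlation). Plin4 (2.74, SE 0.37), the fatty acid translocase Cd36 (2.34, SE 0.21) and Fitm2 (0.93, SE 0.13) were among them. In the list of PPAR alpha targets and fatty acid oxidation, 4 of 31 rose, 25 adjusted over the list alone (median 0.85, adjusted p = 1.55e-11, and adjusted p = 0.432 with an estimated correlation): the pantetheinase Vnn1 (3.07, SE 0.25), Pex11a (1.84, SE 0.24), the uncoupling protein Ucp2 (1.64, SE 0.21) and Decr1 (1.01, SE 0.11). The hormone Fgf21 had 4.10 (SE 0.87) and did not pass. Of 23 lipogenesis genes, the desaturase Fads2 rose (1.71, SE 0.20), the transcription factor Mlxipl fell (-0.80, SE 0.11) and 21 did not pass (median 0.65, adjusted p = 0.000622, and adjusted p = 0.432 with an estimated correlation). Adjusted over the list alone 5 rose and 1 fell.

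Cell cycle genes gave the smallest p of the lists, with 9 of 28 members risen, 0 fallen and 21 risen adjusted over the list alone (median 1.39, 1.12 with bounds, adjusted p = 4.52e-13, and adjusted p = 0.432 with an estimated correlation). The proliferation marker Mki67 rose by 2.44 (SE 0.22), the mitotic kinase Plk1 by 1.82 (SE 0.12) and the replication helicase subunit Mcm2 by 1.80 (SE 0.23). The list's median relative to chow was 0.63 and 0.59 at 6 weeks, 2.26 and 2.15 at 12 weeks, and 1.11 and 1.25 at 20 weeks in the wild type and the knockout. Interferon response genes rose (6 of 28 members, 21 adjusted over the list alone, median 0.82, 0.79 with bounds, adjusted p = 3.73e-11, and adjusted p = 0.432 with an estimated correlation), among them Oas1a (1.48, SE 0.18), the GTPase Igtp (0.85, SE 0.13) and the immunoproteasome subunit Psmb9 (1.26, SE 0.13).

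Markers of other cells moved with the diet. Lipid-associated and recruited macrophage genes rose (3 of 12, 9 adjusted over the list alone, median 1.86, 1.15 with bounds, adjusted p = 4.01e-06, and adjusted p = 0.432 with an estimated correlation), namely Spp1, the monocyte chemokine receptor Ccr2 (at least 1.16-fold) and Ly6c (2.62, SE 0.24). Trem2, a receptor of lipid-laden macrophages, had 2.25 (SE 0.43) and did not pass. Stellate cell and fibrosis genes rose (2 of 26, 10 adjusted over the list alone, median 0.63, 0.54 with bounds, adjusted p = 2.26e-06, and adjusted p = 0.432 with an estimated correlation), with Lrat, which stores vitamin A, at 0.69 (SE 0.10) and the collagenase Mmp13 at 2.06 (SE 0.30, from chow signals not well above background), while Col1a1 had 2.63 (SE 0.67) and did not pass. Kupffer cell markers rose as a list (0 of 19 members, 8 adjusted over the list alone, median 0.46, adjusted p = 0.000628, and adjusted p = 0.548 with an estimated correlation). Antigen presentation genes rose as a list (0 of 17, 4 adjusted over the list alone, median 0.53, adjusted p = 1.01e-06, and adjusted p = 0.432 with an estimated correlation). Inflammatory cytokine genes rose (Ccl2 alone of 18, 3 adjusted over the list alone, median 1.01, 0.62 with bounds, adjusted p = 0.000628, and adjusted p = 0.48 with an estimated correlation). Neutrophil markers rose (Lcn2 alone of 8, 3 adjusted over the list alone, median 0.71, 0.25 with bounds, adjusted p = 0.00102, and adjusted p = 0.432 with an estimated correlation).

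Hepatocellular carcinoma and fetal liver genes rose (4 of 21, 6 adjusted over the list alone, median 0.96, 0.61 with bounds, adjusted p = 0.000286, and adjusted p = 0.432 with an estimated correlation). The members were Ly6d (4.77, SE 0.69), the glypican Gpc1 (3.26, SE 0.18), Spp1 and Lcn2, and the marker Tff3 had -4.11 (SE 1.84) without passing. The 3 members Orm3 (2.66, SE 0.20), Lcn2 and Serpina3n (0.87, SE 0.12) rose among 30 acute phase genes (median 0.14, adjusted p = 0.0446, and adjusted p = 0.701 with an estimated correlation), and 10 rose and 2 fell adjusted over the list alone.

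In the list of xenobiotic metabolism 5 of 26 fell, 0 rose and 21 did not pass (adjusted over the list alone, 8 fell and 2 rose; median -0.31, adjusted p = 0.0217, and adjusted p = 0.48 with an estimated correlation): Cyp3a11 (-1.70, SE 0.23), Cyp3a16 (-1.39, SE 0.18), Cyp2c29 (-0.94, SE 0.11), Cyp2c55 (-2.41, SE 0.24) and the carboxylesterase Ces2a (-2.13, SE 0.19). The mean of the list was -0.16 and 11 of 26 members were positive. Quantile normalization ended its call (adjusted p = 0.0681), and Cyp2b9 stood at 3.79 (SE 1.67) without passing. Bile acid genes fell (1 of 22, the transporter Slco1a1, 4 adjusted over the list alone with 1 risen, median -0.36, adjusted p = 0.00883, and adjusted p = 0.432 with an estimated correlation).

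Male-biased liver genes fell (4 of 19, 14 adjusted over the list alone, median -1.15, adjusted p = 5.68e-09, and adjusted p = 0.432 with an estimated correlation), with Slco1a1 at -5.18 (SE 0.39), Nat8 at -3.09 (SE 0.37), Susd4 at -1.95 (SE 0.29) and Gstp1 at -1.29 (SE 0.15). Without the 20-week arrays, which carried Xist signal and no Y-linked signal, the list's median was -0.86 (adjusted p = 3.5e-07). Female-biased genes were higher as a list (median 1.32, 1.14 with bounds, adjusted p = 0.000134, and adjusted p = 0.432 with an estimated correlation), but the members went both ways: A1bg and Hao2 rose, and Cyp3a41a (-1.19, SE 0.17), Cyp3a44 (-1.59, SE 0.19) and Cyp3a16 fell. A1bg was well above background on the 20-week arrays alone, so its rise rests on those arrays. Adjusted over the list alone 14 rose and 3 fell. Without the 20-week arrays this list's median was 0.36 and its call ended (adjusted p = 0.54), as did that of the sex chromosome genes (median -2.06, 3 of 4 fell, adjusted p = 0.00373; without 20 weeks -0.16, adjusted p = 0.615; adjusted p = 0.432 with an estimated correlation).

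Falls among named genes included Clec2h, a C-type lectin (-6.16, SE 0.85), Slco1a1, the pseudogene Serpina4-ps1 (-4.17, SE 0.53), Obp2a (at least 3.85-fold) and Apobec4 (at least 3.44-fold). Clec2h was well above background on 2 of 6 diet arrays, and Slco1a1 and Serpina4-ps1 on 3 of 6. Their sizes thus rest partly on background. Further rises included Cgref1 (4.16, SE 0.29) and Stap1 (at least 5.84-fold). Adipocyte markers rose as a list (Cidea alone of 8, 3 adjusted over the list alone, median 1.01, 0.22 with bounds, adjusted p = 0.0285, and adjusted p = 0.432 with an estimated correlation). Immediate early genes rose as a list (0 of 20, 0 adjusted over the list alone, median 0.89, adjusted p = 0.00883, and adjusted p = 0.695 with an estimated correlation). T and NK cell markers (0 of 14, 0 adjusted over the list alone, median 0.48, 0.38 with bounds, adjusted p = 0.0454) and sinusoidal endothelial markers (0 of 16, 1 adjusted over the list alone, median 0.21, adjusted p = 0.0419) rose, each with adjusted p = 0.631 with an estimated correlation. The T and NK cell call held in 3 of 10 other settings at the preset correlation, and quantile normalization ended it (adjusted p = 0.0566). The other 15 lists did not pass, at adjusted p from 0.0634 (apoptosis and p53 genes) to 0.988 (circadian clock genes). Among them were endoplasmic reticulum stress genes (median -0.20, adjusted p = 0.0757), complement components (-0.17, adjusted p = 0.327), cholesterol synthesis genes (0.09, adjusted p = 0.6) and glucose production genes (0.02, adjusted p = 0.908). In these lists Cel of the exocrine pancreas (1.04, SE 0.14) and Gpx3 (at least 3.19-fold) rose, and the erythroid enzyme Alas2 (-1.37, SE 0.16) and Osgin1 (-1.95, SE 0.20) fell.

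In total 358 genes passed (236 rose, 122 fell), 282 of them changed at least 2-fold, and 22 of 37 lists passed (18 up, 4 down), 0 with an estimated correlation and 9 by fry. Within a genotype, and so within a slide, their median sizes were 1.42 in the wild type and 1.54 in the knockout, though the genes were chosen on both genotypes together. Without the 20-week arrays limma passed 0 genes (2929 at unadjusted p under 0.05, smallest adjusted p = 0.0875, 2 residual degrees of freedom). Of the 358, 356 kept their sign and their median size was 1.44 in place of 1.49. They were chosen with the 20-week arrays included and the fit reuses all other arrays, so this is no independent check. Of the 22 lists 17 kept their call and the T and NK cell, endothelial and acute phase calls ended (adjusted p = 0.185, 0.147 and 0.185). Leaving out any 1 diet array left 0 genes, except for the wild-type array at 6 weeks, without which 119 were left. Without 1 chow array the comparison rests on a single chow array. Leaving out the wild-type chow array ended the calls of the Kupffer cell (adjusted p = 0.158), cytokine (adjusted p = 0.062), immediate early (adjusted p = 0.178), xenobiotic (adjusted p = 0.0908), adipocyte and bile acid lists (adjusted p = 0.0532 for each). The count of 358 moved between 18 and 1037 with the model terms and the variance prior.

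**Figure D4:**
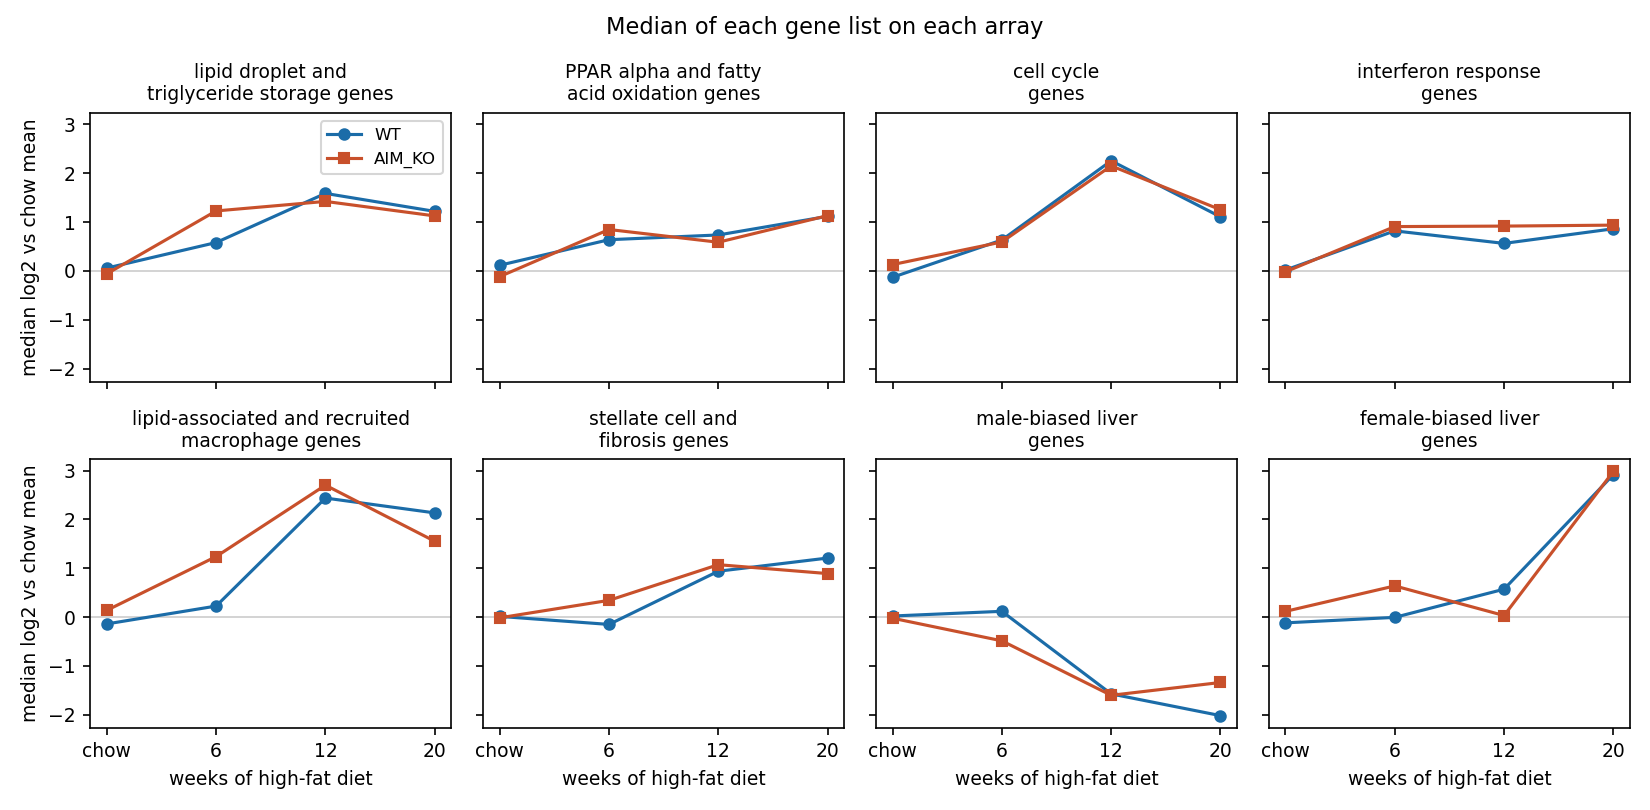
Median log2 level of 8 gene lists on each array relative to the mean of both chow arrays (vertical axis) by weeks of high-fat diet (horizontal axis), in the wild type (circles) and the knockout (squares). The cell cycle list peaks at 12 weeks (2.26 and 2.15), and the female-biased list stands at 2.92 and 2.98 at 20 weeks.

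The comparison of 20 with 6 weeks on the diet addressed how the liver changes as obesity lasts. Both 20-week arrays carried Xist signal without Y-linked signal, and some of the genes that passed are sex-linked: Ddx3y, Eif2s3y and Kdm5d fell at least 46.1-fold, 66-fold and 2.85-fold, and Tsix, the antisense partner of Xist, rose at least 2.19-fold. Female-biased liver genes rose (2 of 21, 17 adjusted over the list alone, 21 of 21 positive, median 3.07, 2.48 with bounds, adjusted p = 2.45e-19, and adjusted p = 0.218 with an estimated correlation), with A1bg at least 100-fold and the transcription factor Cux2 at least 8.22-fold higher. Male-biased genes fell (1 of 19, 13 adjusted over the list alone, median -1.39, adjusted p = 1.15e-11, and adjusted p = 0.472 with an estimated correlation), with Slco1a1 at least 70.9-fold lower. The male-biased genes had fallen by 12 weeks too, between arrays that all carried Y-linked signal (median -1.36 from 6 to 12 weeks, adjusted p = 3.71e-09), and the female-biased list had a median of 0.49 over that step (adjusted p = 0.0154). Both calls ended with an estimated correlation (adjusted p = 0.423 and 0.58), as did every list call from 6 to 12 weeks.

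Other genes that rose were Slc22a26 (at least 19.9-fold), Tmem145 (at least 4.12-fold), Crispld2 (at least 2.26-fold), the receptor Notch3 (at least 2.27-fold), the sialyltransferase St3gal6 (2.75, SE 0.18), the drug transporter Abcb1a (at least 1.52-fold) and Kcnj3 (at least 1.9-fold), and Omd fell at least 6.38-fold. From 6 to 12 weeks Slco1a1 had -5.26, Abcb1a 1.89 and St3gal6 -0.02, whereas A1bg and Cux2 were well above background on the 20-week arrays alone.

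Among lists that passed in both 20 minus 6 and 12 minus 6 weeks, stellate cell and fibrosis genes rose (0 of 26 members, 13 adjusted over the list alone, median 1.07, 0.81 with bounds, and 1.06 by 12 weeks; adjusted p = 3.31e-10, and adjusted p = 0.472 with an estimated correlation), with 2.65 (SE 0.82) for Col1a1 and 2.93 (SE 0.75) for Ccn2, connective tissue growth factor. Lipid-associated macrophage genes rose (0 of 12, 3 adjusted over the list alone, median 1.06, 0.66 with bounds, and 1.62 by 12 weeks; adjusted p = 3.29e-05, and adjusted p = 0.498 with an estimated correlation), with 3.02 (SE 0.57) for Spp1. Hepatocellular carcinoma and fetal liver genes rose (0 of 21, 10 adjusted over the list alone, median 1.83, 1.28 with bounds, and 1.38 by 12 weeks; adjusted p = 6.29e-06, and adjusted p = 0.472 with an estimated correlation). Cholangiocyte and progenitor markers rose (0 of 11, 6 adjusted over the list alone, median 2.32, 1.02 with bounds, adjusted p = 0.00019, and adjusted p = 0.49 with an estimated correlation), with values at least 7.94-fold higher for the keratin Krt7 and 2.43-fold for Tspan8; by 12 weeks their median was 0.35 (adjusted p = 0.273).

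In total 18 genes passed (11 rose, 7 fell), with 18 of 37 lists (15 up, 3 down) at the preset correlation, 0 with an estimated one and 2 by fry. From 6 to 12 weeks limma passed 0 genes (2374 at unadjusted p under 0.05, smallest adjusted p = 0.117), 13 of the 18 had the same sign, 6 of them at least 2-fold, and 13 of the 18 lists kept their call. Those lists also included neutrophil, T and NK cell, sinusoidal endothelial, immediate early, cytokine, antigen presentation and cell cycle genes. Leaving out any single array left 0 to 11 genes.

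The interaction asked whether the diet acted differently without AIM. No gene passed: limma found 0 genes past the threshold and 680 at an unadjusted p under 0.05, against 767 expected by chance, and the smallest adjusted p was 0.348. Without the filter on dim probes 111 genes passed (53 up, 58 down). The genes with the smallest p included the bone sialoprotein gene Ibsp (7.37, SE 0.68, adjusted p = 0.348), the clock output factor Dbp (-3.09, SE 0.37, adjusted p = 0.374, and 0.0485 without the filter), Dand5 (2.27, SE 0.25, adjusted p = 0.348, and 0.0481 without the filter) and Cyp46a1, which hydroxylates cholesterol (-2.22, SE 0.29, adjusted p = 0.403). Over the alternatives the adjusted p of Ibsp ran from 0.0285 (without the filter) to 0.65 (normexp, with 2.42 in place of 7.37), and it was 0.0449 without the knockout array at 20 weeks. The size of 7.37 is no measured one, since the signals of 7.11 in the knockout on chow and of 5.76 and 6.30 in the wild type at 6 and 12 weeks were not well above background. For Ibsp the chow difference alone was at least 7.58-fold lower in the knockout (signal 7.11 against 226). Across genes, the diet's effect in the wild type and in the knockout had a correlation of 0.473. The simulated data recovered 2% of genes with a 2-fold interaction, 36% of those with a 4-fold one and 66% of those with an 8-fold one. They held no change between weeks of diet, which this model counts as error. On the real arrays these shares are likely too high.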

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

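The tests of the sex pattern, the chromosomes and the 6-week knockout array were chosen after the results they concern were seen, while the divisions of the arrays were planned.

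Among the genes with the largest difference in a single week, 12 stood higher in the knockout in 1 week and lower in another. None of these opposite directions was tested, since each rests on 1 array per genotype and week. All values are log2 differences, knockout minus wild type. Moxd1 stood at 9.12 on chow and -6.26 at 6 weeks. Tff3 stood at 4.94 on chow, -4.94 at 6 weeks and 1.23 at 12 weeks. Ibsp went from -5.15 on chow to 2.32 at 6 weeks and 2.53 at 12 weeks, and Adm2 from -5.09 on chow to 4.23 at 20 weeks. The T cell receptor gene Tcra had -4.23 on chow, -2.11 at 6 weeks and 4.56 at 12 weeks, and the sperm protein gene Adam1a had -2.40 on chow, 4.27 at 12 weeks and 1.15 at 20 weeks.

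Between 12 and 20 weeks the actin-bundling gene Espn went from -4.73 to 2.29, the glycosyltransferase gene B4galnt4 from -4.72 to 1.33, Rnf150 from -4.01 to 4.50 and Cuzd1 from -4.54 to 4.35. Phkg1, a phosphorylase kinase subunit, had -3.04 at 6 weeks and 4.67 at 20 weeks, and the B cell receptor-like gene Fcrl1 had 4.66 on chow and -4.73 at 20 weeks. In all of these values except those of Tff3 on chow and at 12 weeks, 1 of both arrays was not well above background, so the sizes are not folds between measured signals.

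The 20-week arrays carried Xist signal and no Y-linked signal in both genotypes. A dim or failed hybridisation would lower the share of probes well above background, but the lower 20-week array had a share 1.23 percentage points above the highest of the others. A gradual effect of the diet would show by 12 weeks, when the mean difference of 3 Y-linked genes from chow was -0.28. The brightest Xist probe, taken after the probe with the highest mean had been tried, which read 892 on the lower 20-week array and 165 on the knockout array at 6 weeks, had a gap of 8.005 between the 20-week arrays and the others (log2), or at least 111-fold over the lowest signals well above background, as livers of female mice at 20 weeks would give, so the 20-week animals may have been female. Age, sex and time on the diet then change together at that step, and the labels used here give no sex.

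The genotype differences gathered on chromosomes 3 and 14. A slide or scan effect would spread evenly over the chromosomes, but the permutation p of an even spread was 0.00014 for genes with an unadjusted p under 0.01; that limit was chosen after 0.001 had been tried, where the permutation p was 0.0444. Sequence variants under the probes would lower knockout signals, yet the genes higher in the knockout were also gathered on chromosome 3 (one-sided Fisher exact p = 0.000263), and for the 22 genes of chromosome 3 lower in the knockout such variants and lower expression cannot be told apart without the sequences (68.8% of these chromosome 3 genes were lower, against 78.9% on the other chromosomes). On chromosome 3 the genes lay closer to Cd5l than others (one-sided permutation p = 0.0165, and permutation p = 0.225 at the limit of 0.001), as a segment of another strain carried along with the targeted allele would give. Such a segment may underlie part of the differences, although neighbouring paralogs such as Hsd3b1, Hsd3b3 and Hsd3b6 are not independent, and chromosome 14 does not carry Cd5l.

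On the knockout array at 6 weeks, female-biased liver genes stood high and male-biased ones low; a female animal would lack Y-linked signal, but 3 Y-linked genes differed from the other 5 arrays that carry it by a mean of -0.122. A scaling of the array would move both lists the same way, yet with quantile normalization (taken after Cyp2b9 alone had been tried) the female-biased median lay 0.93 above the male-biased one in the difference between the 6-week arrays. With the sex-biased lists left out, this array stood at 0.263 on the wild type's axis from chow to 12 weeks and the wild-type array at 6 weeks at 0.118 on the knockout's axis, 0.145 apart on different scales, and at 0.529 and 0.338 on 1 common axis. Of 21 female-biased genes 4 were higher on it than on the wild-type array at 12 weeks (two-sided exact sign test p = 0.0072, genes not being independent). The list's median relative to chow was 0.64, against 0.57 on that wild-type array and 0.03 on the knockout array at 12 weeks. Taken gene by gene the order was the other way. The median difference of the 6-week knockout array was -0.302 from the wild-type and -0.119 from the knockout array at 12 weeks. A liver further along the change of the diet may underlie the part outside these lists and, less clearly, the female-biased part, but with 1 knockout array at 6 weeks the loss of AIM and a difference between animals cannot be told apart.

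The genotype comparison gave 5 genes, and the highest count among the 7 other divisions of the 4 week pairs was 0. The 8 divisions are too few for a share under 0.05. For lists the real count was 4 and the highest other 19, with 7 of 8 divisions giving at least as many. This points to a structure of the samples or to list members that move together beyond the preset correlation of 0.01. That correlation was estimated at 0.317 to 0.508 for the 4 lists. With an estimated correlation 0 of 37 lists passed for the real division, so the 4 calls rest on the preset value. A structure of the samples was not tested, nor were the other divisions with an estimated correlation. Divisions that part 2 of the pairs, 24 in number, reached 11 genes and 18 lists.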

How the results depend on the processing

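The fits without the 20-week arrays, with 12 in place of 20 weeks and without genes near Cd5l, and the list tests for 20 minus 6 weeks with their alternatives, were tests chosen after seeing the data. The cause of a change below was not tested unless it is named.

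Named genes kept their direction in 108 of 108 combinations of gene and alternative for genotype, 417 of 417 for the diet, 266 of 271 for 20 minus 6 weeks and 124 of 124 for the interaction. Their side of the threshold stayed in 80, 147, 117 and 117 of these. The genes were picked on these same arrays for size, sign or small p, so a kept direction is no independent check. With 12 in place of 20 weeks A1bg (-0.14), Tsix (-0.33), St3gal6 (-0.016), Kcnj3 (-0.52) and Ddx3y (0.076) had the other sign. A1bg, Tsix and Kcnj3 were not well above background at 6 or 12 weeks, so their sign there is that of background, and St3gal6 and Ddx3y lay within 1 SE of 0. No scaling moved the median of all genes by more than 0.0432.

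The 5 genotype genes became 3 among genes well above background on all 8 arrays and 1 in the 3 weeks of diet alone. Without any 1 week pair the count was 1, and for lists it ranged from 6 to 16 (11 higher and 5 lower without 20 weeks). The 358 diet genes became 233 with quantile normalization, 693 with normexp, 27 without a filter on dim probes, 905 among genes well above background on all 8 arrays, 1037 with an intensity trend and robust prior, 18 with chow or diet as a factor of 2 levels and 119 with a linear trend. Leaving out 1 diet array gave 0, except for the wild-type array at 6 weeks (119), with 2 residual degrees of freedom, and 20 to 22 lists. Without both 20-week arrays it gave 0 with limma, 2929 genes being at unadjusted p under 0.05.

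The 18 genes of 20 minus 6 weeks became 86 with normexp, 8 without a filter, 36 on all 8 arrays, 38 with the mean of a gene's probes, 84 with the trend and robust prior and 0 to 11 without 1 array. With 12 in place of 20 weeks the count was 0, with 2374 at unadjusted p under 0.05. The interaction count of 0 became 111 without a filter on dim probes and 0 to 3 without 1 array; it could not be fitted without a chow array. The authors' value table gave 5, 357, 18 and 0 genes in these comparisons.

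An estimated correlation passed 0 lists for genotype, 0 for the diet and 0 for 20 minus 6 or 12 minus 6 weeks. Quantile normalization kept 4 of 4 genotype lists and 20 of 22 diet lists, ending the calls of T and NK cell markers (adjusted p = 0.0566) and xenobiotic genes (adjusted p = 0.0681). Leaving out 1 array also ended the diet calls of T and NK cell markers (adjusted p up to 0.178), sinusoidal endothelial markers (up to 0.306), acute phase genes (up to 0.33), xenobiotic genes (up to 0.223) and adipocyte markers (up to 0.0851).

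The counts at least 2-fold apart at 0, 6, 12 and 20 weeks became 400, 352, 216 and 205 with normexp, whose offset shrinks dim differences by construction, and 480, 395, 184 and 155 among genes well above background on all 8 arrays. A 1.5-fold threshold gave 2499, 2458, 1693 and 1527, and a 3-fold threshold 537, 467, 368 and 287. Without a filter the count was 1067 at 12 weeks and 1094 at 20 weeks. Signal over background limits these counts: both arrays were well above background for 550, 489, 287 and 314 of the genes at the 2-fold threshold.

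No paired analysis was possible by replicate number because the groups share only 1 such number, while the genotype fit pairs the arrays by week. A slide block was not run, since slide and genotype coincide.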

Other observations

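The values from 6 to 12 weeks and the chromosome 14 genes below come from tests chosen after seeing the data.

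From 6 to 12 weeks on the diet, in arrays that all carry Y-linked signal, oxidative stress and NRF2 genes rose as a list (median 0.68, adjusted p = 1.38e-06), as did inflammatory cytokine genes (1.21, adjusted p = 9.13e-07), lipid droplet genes (0.62, adjusted p = 0.000412) and Kupffer cell markers (0.38, adjusted p = 0.00545). Bile acid genes (-0.47, adjusted p = 0.0154) and complement components (-0.32, adjusted p = 0.0266) fell as lists. These calls use the preset correlation, and each ended with an estimated one (adjusted p from 0.397 to 0.793). The NRF2, lipid droplet, Kupffer cell, complement and bile acid lists did not pass from 6 to 20 weeks (adjusted p = 0.103, 0.113, 0.102, 0.103 and 0.32), and the difference between both steps was not tested.

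Cd5l itself had 0.87 (SE 0.14) in the diet comparison of both genotypes and did not pass (adjusted p = 0.0538). Cfd, adipsin of fat cells, had -6.96 (SE 0.89) from 6 to 20 weeks and did not pass (adjusted p = 0.0835). Endoplasmic reticulum stress genes fell as a list over that step (median -0.56, adjusted p = 0.000599, and adjusted p = 0.649 with an estimated correlation).

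On chromosome 14, 19 genes had an unadjusted p under 0.01 for genotype against 8.39 expected, and all 19 were lower in the knockout (Fisher exact p = 0.000791, adjusted over the chromosomes 0.00831). Of such genes on all chromosomes but 3, 78.9% were lower. At the limit of 0.05 there were 36 against 29.2 expected (Fisher exact p = 0.114). On chromosome 3 there were 32 against 11.8 expected at 0.01.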
